A study of Mus musculus with 4 samples.

How the data were processed

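RNA from pooled whole mouse corneas was hybridised to 4 Affymetrix 3' expression arrays, 1 for each of 4 groups: mock-infected without diphtheria toxin (DT), infected with HSV-1 without DT, mock-infected with DT, and infected with DT. The mice were bone marrow chimeras on the BALB/cJ strain, reconstituted with marrow that carries a diphtheria toxin receptor transgene under the CD11c (Itgax) promoter. DT was given 6 weeks after marrow transfer and 2 days before infection. Group and toxin status were taken from the infection characteristic of each sample, and the signal columns were matched through the sample titles. The number of corneas in each pool and the time between infection and collection are not given in the sources used here.

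The authors deposited a signal intensity for each of 45101 probe sets, a detection call (present or not) and a change call for each of 4 array pairs, per the file headers. The signals came from GCOS 1.4, per the submitters' processing notes. The trimmed mean over the middle of each array, leaving out 2% of the signals at either end, was 150.0 on all 4 arrays, so the deposited signals were taken as already scaled and were not scaled again. Other steps behind the signals are not given in the sources used here. A second deposited table of the whole series held the same signals, cell for cell, on all 4 arrays. The authors' deposited table also carries a flag of 1 on 262 probe sets and of 2 on 297.

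Gene symbols came from a probe-to-gene table and RefSeq gene names of assembly GRCm38.p6. Of the probe sets, 34958 had a single symbol, 932 had several, 9160 were not listed and 64 were Affymetrix controls, and 204 of those with a single symbol had a gene number that the RefSeq table does not hold. Each of the 18194 genes was represented by its probe set with the highest mean log2 signal. Signals without a present call were raised to the lowest present signal of their array where they lay below it, and log2 ratios of array pairs were taken. A gene entered a count if its probe set was called present on the brighter array of the pair and reached the 10th percentile of that array's present signals. A ratio of 2-fold or more then counted as higher or lower. A fold against an array without a present call uses the raised signal, or the signal itself where it lay above this floor. Such a fold is no lower bound, since many signals without a present call lay above the floor. The fold with the floor at the 10th percentile of present signals is given beside it. A fold between 2 present calls is given alone, also where the dimmer signal lay below that percentile. Where the brighter array had no present call, no fold is given.

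With 1 array per group no test across samples was run, and no p-value is reported. The difference between the infection responses with and without DT is the difference of their log2 ratios and was not tested either. The spread that the arrays can show is that between probe sets of the same gene. Its SD was 0.35 on the log2 scale for infection without DT, 0.34 for infection with DT, 0.25 for DT in infected corneas and 0.42 for DT in mock corneas. It holds no variation between animals or pools.

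The comparisons, the counting rule, 34 gene lists and the rule for naming genes were set before the data were examined. The naming rule took the 10 largest rises and the 10 largest falls among genes present on both arrays and at or above the 25th percentile of present signals on the brighter array. It added up to 5 genes per direction that were present on 1 array only, with the same brightness limit, the 2 to 4 present members with the largest change of each list described, and Itgax, Ncr1, Gzmb, Ifnb1 and Ifng in every comparison. For the difference of responses it took the 10 largest differences in each direction among genes present on both arrays of at least 1 of the 2 infection pairs. Predicted genes without a proper symbol were counted but not named. Of 577 distinct symbols on the lists, 527 were measured and 50 were not analysed here. A list's median log2 ratio was taken over members called present on at least 1 of the arrays compared and set beside the medians of 10000 random lists of the same size, matched on mean signal. This ranks the list among genes of the same arrays and is no test across samples.

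The counting was tested on simulated arrays that carried the spread between probe sets. With 100 genes changed at each size, it recovered 95% of 4-fold and 89% of 2.83-fold changes for infection without DT, among 12459 simulated genes. The values were 93% and 85% for infection with DT among 12755 genes, 91% and 94% for DT in infected corneas among 13066, and 92% and 84% for DT in mock corneas among 12454. Of the unchanged genes, 0.391%, 0.183%, 0% and 1.27% were called in these comparisons in the same order. Both simulated arrays of a pair had the same present calls, and all genes had the same SD. These shares therefore do not cover folds against an array without a present call, nor the larger spread of dim genes. The simulated arrays also held no variation between animals or pools, so the shares are no rates of false calls for the real comparisons.

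The alternatives set in advance were quantile normalization, centring each array on the median of probe sets present on all 4 arrays, a pseudocount of 50, a floor at the 10th percentile of present signals, the mean of all probe sets of a gene and, for list medians, all measured members. Counts were also taken without a filter, with the 25th percentile filter and at 3-fold. After the data were seen, 3 alternatives were added: the mock array of the other DT arm as denominator, a change beyond both mock arrays, and leaving out genes 2-fold apart between the mock arrays. With the mock array of the other arm, the arrays compared differ in DT as well as in infection. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.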

Results

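Transcript levels in mouse corneas were measured on 4 arrays, 1 each for mock-infected and HSV-1-infected corneas of CD11c-DTR bone marrow chimeras that had or had not received DT, the toxin that kills cells bearing its receptor. The series asks, by its title, what early dendritic cells contribute to the natural killer (NK) cell response in the infected cornea. Each group was a single pool of whole corneas, so there is no replicate check on any value, and all comparisons are between arrays. Present calls covered 57.9% of probe sets on the mock array without DT, 62.2% on the infected array without DT, 60.5% on the mock array with DT and 62.2% on the infected array with DT. The 10th percentile of present signals lay at 16.0, 16.6, 18.9 and 16.7 in the same order.

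Itgax, which encodes CD11c and whose promoter drives the toxin receptor in the donor marrow, had signals of 16.7 (mock without DT), 31.4 (infected without DT), 14.6 (mock with DT, not called present) and 21.4 (infected with DT). These lie close to the detection floor, and the transgene itself was not analysed here. With DT the Itgax signal was 1.47-fold lower in infected corneas. The authors' deposited change calls give no change for Itgax with DT in infected or in mock corneas. Of the MHC class II genes, carried by dendritic cells, macrophages and B cells, some were well above the floor: Cd74, the class II invariant chain, had signals of 374.9, 1075.1, 232.3 and 199.7 in the same order, and H2-Aa, a class II alpha chain, had 213.6, 676.5, 111.5 and 107.7. Others on that list were near it, such as Ciita with 18.5, 15.5, 8.0 and 8.1.

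The pools also differed in transcripts of tissue around the corneal epithelium. Skeletal muscle genes were low on the mock array without DT: Acta1, skeletal muscle actin, had signals of 59.8, 720.7, 752.7 and 265.1, and Ckm, muscle creatine kinase, 36.9, 391.6, 383.2 and 117.7. Kera, the keratocan core protein of keratocytes, was not called present on that array (14.9) and had 484.5, 176.2 and 165.6 on the others. Lens and retina transcripts were bright on all 4 arrays. The lens crystallin Crybb2 had signals of 8048.6, 8754.5, 7488.7 and 8397.5, and the rod phosphodiesterase Pde6b had 2288.9, 4694.8, 5137.8 and 4816.2. Across probe sets, the 2 infected arrays had the highest correlation of log2 signals (r = 0.989) and the 2 mock arrays the lowest (r = 0.943). Probe sets are not independent replicates.

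**Figure D1:**
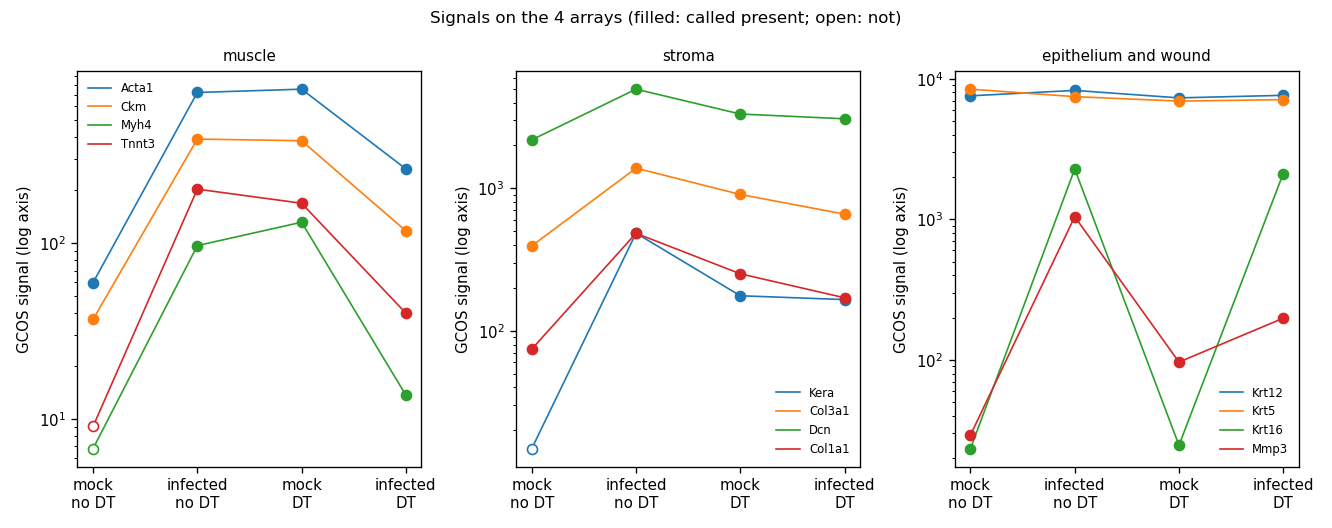
Signals (log axis) of muscle, stromal, and epithelial or wound genes on the 4 arrays, 1 point per array with a line joining the points of a gene, filled where called present and open where not. Acta1 lies at 59.8 on the mock array without DT and at 720.7, 752.7 and 265.1 on the others, while Krt16 lies at 23.4 and 24.7 on the mock arrays and at 2279.0 and 2115.9 on the infected arrays.

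Infection without DT was compared with mock infection to give the corneal response with CD11c-positive cells in place. Most interferon-stimulated genes, chemokines, neutrophil and macrophage genes and the wound keratins Krt16 and Krt17 were higher in infected corneas. Among type I interferon stimulated genes, 17 of 30 rose, 0 fell and 13 did neither, with a median log2 ratio of 1.13 that exceeded all 10000 random lists. Mx1, a GTPase that blocks viral replication, rose 16.7-fold, Rsad2 (viperin) 10.8-fold, Isg20, an exonuclease, 9.73-fold and Ifi204, a DNA sensor, 8.34-fold. Where the dimmer array of a pair had no present call, its signal was raised to the lowest present signal of that array only if it lay below it. Such a fold is no lower bound and has no rank, as signals without a present call reached up to 65.3 at their 99th percentile on the mock array without DT, and the fold with the floor at the 10th percentile of present signals follows it in square brackets. Of 24 interferon gamma induced genes 14 rose and 0 fell, among them the CXCR3 ligands Cxcl9 (59.8-fold [6.35-fold]), Cxcl10 (28.3-fold [28.3-fold]) and Cxcl11 (24.5-fold [18.8-fold]) and the GTPase Iigp1 (7.67-fold).

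NK cell markers were detected at low signals. Of 12 present members 5 rose, 0 fell and 7 did neither, with a median log2 ratio of 1.01 that exceeded 9728 of 10000 random lists, and of 0.07 with the floor at the 10th percentile. Gzmb, a cytotoxic granule protease, rose 43.4-fold [4.61-fold] to a signal of 73.7, the activating receptor gene Klrk1 26.7-fold [2.84-fold] to 45.4 and Gzma 8.28-fold [5.12-fold] to 82.0. Ifng, the NK and T cell interferon, rose 5.73-fold [1.72-fold] to 27.5. T cells also carry granule proteases and Ifng, and of 7 present T cell markers 3 rose (median 0.78, and 0.33 with that floor). Ncr1, the NK receptor NKp46, had signals of 11.5 without a present call in infected and 7.8 in mock corneas, and Ifnb1 had 23.4 and 16.4. Of 12 NK attracting chemokines and NK activating cytokines 8 rose, among them Ccl7 (7.29-fold [7.29-fold]), and 1 fell. In the chemokine list 16 of 23 rose and 1 fell, with the neutrophil chemoattractant Cxcl5 up 77.8-fold [8.27-fold].

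Of 8 MHC class II genes 4 rose (median log2 ratio 1.01), with H2-Aa up 3.17-fold, Cd74 2.87-fold, H2-Eb1 2.53-fold and the lysosomal protease Ctss 2.02-fold. Among macrophage and monocyte markers 14 of 20 rose and 0 fell (median 1.70), including the Fc receptor Fcgr1 (10.7-fold), the chitinase-like gene Chil3 (9.78-fold [2.20-fold]), the chemokine receptor Ccr2 (9.28-fold) and C1qb (5.06-fold). Neutrophil markers rose in 6 of 10 cases (median 2.01, and 1.05 with the floor at the 10th percentile), with Csf3r up 25.5-fold [4.31-fold], S100a9 20.6-fold and S100a8 13.0-fold. Dendritic and Langerhans cell markers rose in 3 of 9 cases, the lectins Clec4n (2.68-fold [2.46-fold]) and Clec10a (2.05-fold [1.36-fold]) and the actin bundler Fscn1 (2.38-fold), and Itgax was 1.88-fold higher. Of 14 acute phase and antimicrobial genes 11 rose and 1 fell, with Hp (haptoglobin) up 33.4-fold [3.54-fold] and Saa3, a serum amyloid, 25.1-fold. Of 18 inflammatory cytokine genes 8 rose and 1 fell, with Il6 up 20-fold [2.12-fold] and the prostaglandin synthase Ptgs2 7.51-fold.

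Of 16 genes on the wound and stress list 10 rose, among them the wound keratin Krt16 (97.4-fold), the matrix proteases Mmp3 (35.8-fold) and Mmp13 (34.1-fold [10.6-fold]) and the cornified envelope precursor Sprr1b (21.2-fold [2.26-fold]). Among corneal epithelial genes 4 of 21 fell and 1 rose. Dsg1a, a desmosomal cadherin, fell 4.87-fold, Slurp1, a secreted immunomodulator, 3.99-fold and the epithelial transcription factor Ehf 2.30-fold, while Krt14, a basal cell keratin, rose 2.28-fold. The late cornified envelope gene Lce3c fell 18.8-fold [18.8-fold] and its relative Lce3a 6.38-fold, Ces1d, a carboxylesterase, 5.96-fold, and Cyp24a1, which inactivates vitamin D, 5.20-fold.

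In all, 1439 genes were higher and 339 lower of 13167 compared. Genes of other tissue moved with infection here: 7 of 11 muscle genes rose (median log2 ratio 3.41; Tnnt3 22.3-fold [12.7-fold], Acta1 12.1-fold), as did 12 of 20 stromal genes (median 1.16; Kera 32.5-fold [30.3-fold], Col1a1 6.50-fold) and 10 of 16 vessel genes (median 1.17; Cdh5 4.61-fold [2.85-fold], Emcn 4.56-fold), and muscle genes (Myl1, 26.2-fold; Mb, myoglobin, 14.8-fold) and the adipocyte gene Fabp4 (13.7-fold) were among the 10 largest rises. Against the mock array with DT, an alternative added after the data were seen, 425 genes were higher and 112 lower, and 265 were higher and 24 lower than both mock arrays. With that denominator the muscle median was 0.08, the stromal median 0.52 and the vessel median -0.14, 8 of 20 macrophage markers (median 0.84), 4 of 11 NK markers (0.40) and 1 of 9 dendritic cell markers (0.35) were higher, the chemokine median was 1.28, the wound list median 0.81 and the corneal epithelial median -0.01. The type I interferon stimulated median was 2.14, with 30 of 30 genes higher, and the interferon gamma induced median 2.00, with 20 of 24 higher. Other probe sets of some named genes gave log2 ratios more than 1 from those used: Cxcl9 3.67, Cxcl11 1.95, Fcgr1 1.95, Ccr2 0.42 to 4.34, H2-Aa -1.46 to 1.98, Ckm 0.37 and Cyp24a1 -0.87. Centring the arrays shifted the median over all genes in this comparison by -0.125 on the log2 scale and kept the direction of every list median and gene named here.

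**Figure D2:**
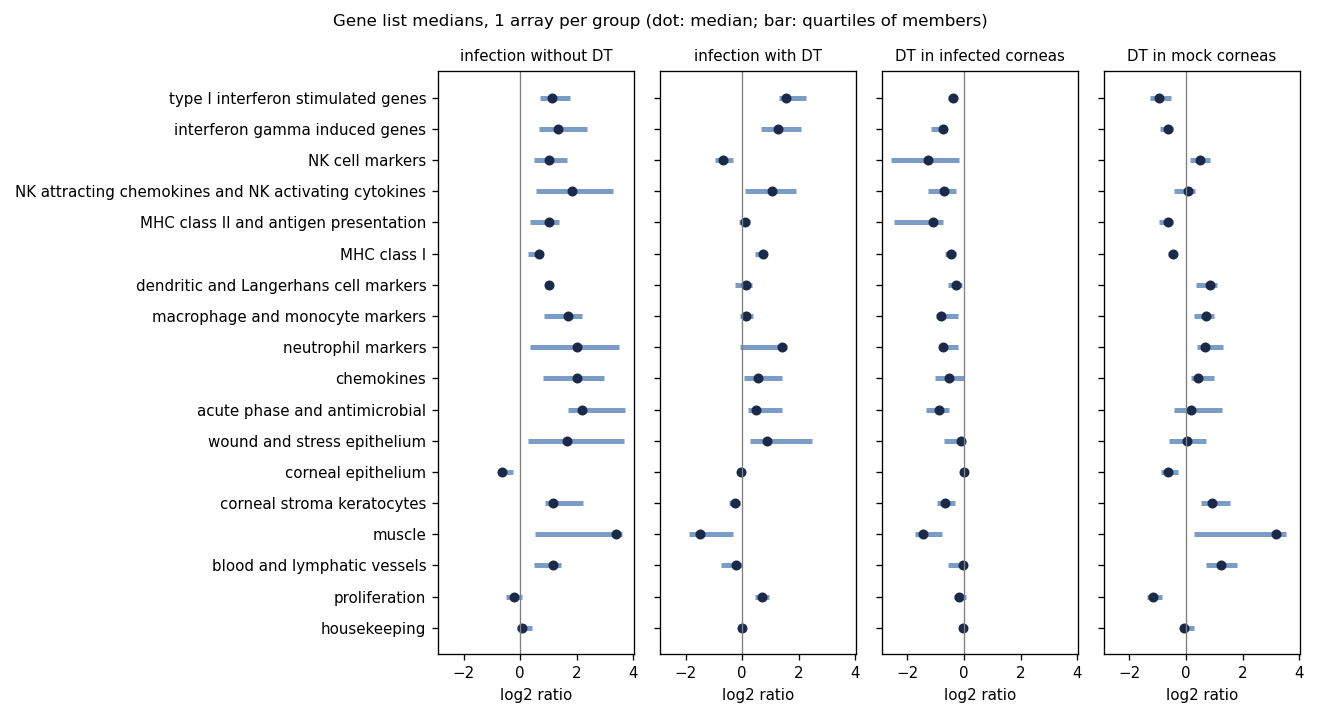
Median log2 ratio (dot) and quartiles of members (bar) of 18 gene lists in the 4 comparisons of array pairs, x axis in log2 units. The type I interferon stimulated genes have medians of 1.13 and 1.56 in the infection comparisons, MHC class II genes 1.01 without DT and 0.10 with DT, and muscle genes 3.41 and -1.48.

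Infection with DT was compared with mock infection with DT to give the response after the toxin. Most interferon-stimulated genes and the wound keratins Krt16 and Krt17 were again higher in infected corneas, while MHC class II genes and most macrophage markers were within 2-fold of the mock array with DT. Of 30 type I interferon stimulated genes 26 rose and 0 fell (median log2 ratio 1.56), among them Rsad2 (10.8-fold), Ifi204 (7.96-fold), Mx1 (7.64-fold [7.64-fold]) and Ifit3 (6.64-fold). Of 23 interferon gamma induced genes 13 rose, including Cxcl10 (13.2-fold), Cxcl11 (6.76-fold [6.23-fold]) and Iigp1 (5.44-fold), and Cxcl9 had a signal of 20.4 without a present call. Krt16 rose 85.7-fold, Krt17 8.82-fold (log2 ratio 1.47 for its other probe set), Mmp13 13.6-fold, Sprr1b 8.50-fold [1.17-fold], Saa3 14.9-fold and the neutrophil chemoattractant Cxcl1 7.54-fold. On the mock array with DT, the present signals of Mmp13 (3.3), Ifi204 (12.1) and Cxcl10 (16.5) lay below the 10th percentile (18.9). Their folds would be smaller with the floor at that percentile. Slfn4, an interferon-inducible Schlafen gene (9.58-fold), Slfn1 (17.6-fold [2.42-fold], with a log2 ratio of 0.55 for its other probe set), Il18bp, which neutralises IL-18 (9.92-fold [3.10-fold]), and Mlkl, the effector of necroptosis (8.07-fold [7.60-fold]), rose as well.

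None of 8 MHC class II genes reached 2-fold (median 0.10), and Cd74 had signals of 199.7 in infected and 232.3 in mock corneas. None of 7 dendritic cell genes and none of 5 present NK markers was counted as changed either. The NK marker Klrc1 was 3.09-fold [1.13-fold] lower but below the brightness limit for counting. Gzmb, Ifng and Ncr1 were not called present on either array of this pair. Itgax was 1.47-fold [1.13-fold] higher, and Ifnb1 was 1.22-fold higher. Of 20 macrophage markers 3 rose (median 0.13), Chil3 4.06-fold [1.72-fold], Fcgr1 2.59-fold and Ccr2 2.22-fold. Of 9 neutrophil markers 5 rose (median 1.43, and 0.44 with the floor at the 10th percentile), including Csf3r 3.85-fold [1.97-fold] and S100a9 3.40-fold. Of 21 chemokines 9 rose, and of 13 acute phase genes 4 rose. Of 21 proliferation genes 5 rose, among them the helicase subunits Mcm3 (2.93-fold) and Mcm6 (2.52-fold) and the ribonucleotide reductase subunit Rrm2 (2.53-fold).

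In this pair 214 genes were higher and 157 lower of 13022 compared. Muscle genes moved the opposite way to the pair without DT: 7 of 12 fell (median log2 ratio -1.48; Actn3 11.8-fold [1.91-fold], Myh4 9.62-fold, Tnnt3 4.21-fold), with Myl1 down 8.43-fold, Fabp4 7.64-fold (log2 ratios of -3 to 0.36 for its other probe sets) and the adipokine gene Adipoq 37.1-fold [5.77-fold]. None of 20 stromal genes reached 2-fold. Lce3c fell 13.7-fold [13.1-fold] and Lce3a 6.07-fold. Muc5ac, a goblet cell mucin, fell 13.0-fold [8.58-fold] and Alas2, an erythroid haem enzyme, 6.97-fold [6.97-fold], both detected on the mock array with DT alone among the 4. Against the mock array without DT, 1380 genes were higher and 392 lower, and 100 were higher and 29 lower than both mock arrays. With that denominator 11 of 30 type I interferon stimulated genes (median 0.65), 8 of 23 interferon gamma induced genes (0.60), 8 of 20 macrophage markers (0.78) and 11 of 21 chemokines (1.39) were higher and 2 of 8 MHC class II genes (-0.65) lower. The dendritic cell median was then 0.76, the NK median -0.15, the acute phase median 0.996, the wound list median 1.41, the corneal epithelial median -0.64, the stromal median 0.66, the muscle median 1.30 and the proliferation median -0.40.

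Infected corneas with and without DT were compared for the effect of the toxin during infection. Lower with DT were 4 of 8 MHC class II genes, 4 of 10 NK markers, 5 of 20 macrophage markers and 8 of 11 muscle genes, while 29 of 30 type I interferon stimulated genes were within 2-fold. Of 8 MHC class II genes 4 fell (median log2 ratio -1.09, below all 10000 random lists), H2-Eb1 6.47-fold, H2-Aa 6.28-fold, Cd74 5.38-fold and H2-Ab1 2.36-fold, and H2-Ea fell 5-fold. Other probe sets gave log2 ratios of -2.50 to -2.07 for H2-Ab1 (-1.24 used) and -4.59 for H2-Ea (-2.32 used). Of 10 present NK markers 4 fell and 0 rose (median -1.29, below all 10000 random lists), Gzma 10.1-fold [4.91-fold], Gzmb 9.45-fold [4.41-fold], Nkg7, a cytotoxic granule gene, 6.93-fold [1.12-fold] and Klrk1 3.91-fold [2.72-fold]. All 4 were called present on the infected array without DT alone, and with the floor at the 10th percentile of present signals the NK median was -0.01. In the same pair 1 of 7 T cell markers (median -0.52, and 0.01 with that floor) and 4 of 6 mast cell and eosinophil markers (median -1.25, and -0.39 with that floor) fell. Ifng fell 12.5-fold [1.65-fold], from 27.5 to a signal of 0.5 without a present call, and Ms4a4b, a T and NK cell membrane protein gene, 9.06-fold [6.13-fold]. The authors' deposited change calls give a decrease for Gzma and Gzmb and no change for Ifng, Klrk1 and Nkg7, which are not called increased or decreased in any pair. Ncr1 was not called present on either array, Ifnb1 was 1.46-fold lower and none of 9 dendritic cell genes reached 2-fold.

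Of 24 interferon gamma induced genes 8 fell (median -0.73), including Cxcl9 (4.98-fold [4.98-fold]), the tryptophan-degrading enzyme Ido1 (2.64-fold), Cxcl11 (2.56-fold) and the guanylate-binding protein gene Gbp6 (2.53-fold). Of 30 type I interferon stimulated genes 1 fell, Isg20 by 2.53-fold, and the median was -0.40, still below all 10000 random lists. Of 12 NK attracting chemokines and cytokines 5 fell, among them Ccl5 (2.78-fold) and Cxcl10 (2.35-fold). Of 20 macrophage markers 5 fell (median -0.80), including Ccr2 (3.49-fold, with log2 ratios of -1.89 to -0.36 for its other probe sets), Ms4a7 (3.06-fold), Aif1 (2.83-fold) and Fcgr1 (2.74-fold). None of 10 neutrophil markers reached 2-fold, with a median of -0.73. Of 14 acute phase genes 6 fell, among them Saa2 (5.44-fold [1.34-fold]), Saa1 (3.84-fold) and Saa3 (3.79-fold), and of 16 wound genes 2 fell, Mmp3 (5.27-fold) and Mmp13 (3.80-fold). Krt16 had signals of 2115.9 with and 2279.0 without DT.

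Muscle and stromal genes fell with the immune genes: 8 of 11 muscle genes (median -1.44; Myl1 9.59-fold, Myh4 7.08-fold, Smpx 6.61-fold) and 5 of 20 stromal genes (median -0.66; Kera 2.93-fold, Col1a1 2.84-fold). None of 16 vessel genes (median -0.02) and none of 21 corneal epithelial genes reached 2-fold. Among the genes that rose were the kinetochore gene Ska1 (2.85-fold), the transcription factor gene Sox30 (2.52-fold), the transmembrane collagen Col25a1 (2.50-fold), the chromatin protein Hmga2 (2.29-fold), the endothelin Edn2 (2.26-fold) and the growth factor Nrg1 (2.05-fold). In all, 35 genes were higher and 247 lower of 13173 compared. Of the 35, 7 carry an increase call in the authors' deposited table, and Ska1 carries no change. Leaving out genes 2-fold apart between the mock arrays left 23 and 128. With the floor at the 10th percentile 13 were higher and 173 lower, and with a pseudocount of 50 the counts were 0 and 59.

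**Figure D3:**
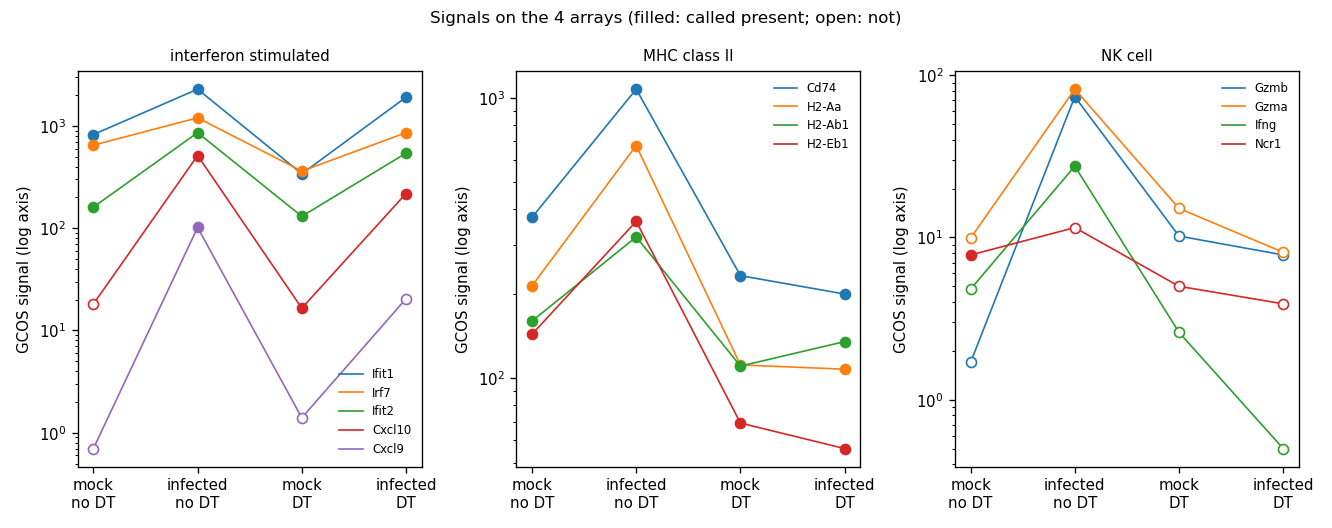
Signals (log axis) of interferon-stimulated, MHC class II and NK cell genes on the 4 arrays, 1 point per array with a line joining the points of a gene, filled where called present and open where not. Cd74 lies at 1075.1 on the infected array without DT and at 199.7 on the infected array with DT, and Gzmb, Gzma and Ifng are called present on the infected array without DT alone.

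Mock corneas with and without DT were compared for the effect of the toxin without virus. Lower with DT were 14 of 21 proliferation and 14 of 30 type I interferon stimulated genes, and higher were 7 of 11 muscle, 9 of 20 stromal and 10 of 15 vessel genes. The mock array with DT, also the denominator for infection with DT, stood apart in some spike-in transcripts, as the last paragraph describes. Of 21 proliferation genes 14 fell and 0 rose (median log2 ratio -1.18, below all 10000 random lists), among them Cdc20, an activator of the anaphase-promoting complex (2.87-fold), Rrm2 (2.85-fold), cyclin Ccna2 (2.79-fold) and the checkpoint kinase Bub1 (2.78-fold). Tk1, a thymidine kinase, fell 3.39-fold, the exonuclease Exo1 4.37-fold and the cohesion genes Esco2 and Cdca5 3.74-fold and 3.52-fold. Also among the largest falls were Smco3 (4.62-fold), Gbp8 (4.09-fold), Neu3 (3.78-fold) and Klhl42 (3.72-fold). Exo1, Gbp8 and Neu3 had signals of 11.6, 14.4 and 10.5 with DT, below the 10th percentile of present signals of that array (18.9). Of 30 type I interferon stimulated genes 14 fell and 1 rose (median -0.94), with Zbp1, a sensor of Z-form nucleic acid, down 3.32-fold, Oasl1 2.80-fold, Usp18 2.67-fold and Ifit3 2.67-fold, and Isg20 up 2.17-fold. Of 22 interferon gamma induced genes 4 fell (median -0.64).

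Of 8 MHC class II genes 2 fell (median -0.63, below 9984 of 10000 random lists), the class II transactivator gene Ciita (2.31-fold) and H2-Eb1 (2.07-fold), while H2-Aa was 1.92-fold and Cd74 1.61-fold lower. Ciita had signals of 18.5 without and 8.0 with DT, where the 10th percentiles of present signals were 16.0 and 18.9. It carries no change in the authors' deposited table. With the floor at the 10th percentile the MHC class II median was -0.56. Macrophage markers were higher in 5 of 19 cases and lower in 0 (median 0.69), with Csf1r up 2.23-fold and C1qb 2.21-fold. Of 7 dendritic cell genes 2 rose, Clec10a (2.53-fold [1.68-fold]) and Cd83 (2.40-fold [2.40-fold]), and Itgax had signals of 14.6 without a present call and 16.7. No fold is given for Gzmb, Ifng and Ifnb1, whose brighter signal had no present call, and Ncr1 had signals of 5.0 without a present call and 7.8. Of 7 NK markers 1 rose, Eomes, a T-box transcription factor (2.24-fold).

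Of 11 muscle genes 7 rose (median 3.17; Myh4 19.4-fold [8.24-fold], Tnnt3 18.6-fold [10.6-fold], Acta1 12.6-fold, Ckm 10.4-fold with a log2 ratio of 0.45 for its other probe set), as did 9 of 20 stromal genes with 1 lower (median 0.93; Kera 11.8-fold [11-fold], Cd34 4.95-fold, Col6a1 4.76-fold) and 10 of 15 vessel genes (median 1.23; Cdh5 5.38-fold [3.33-fold], Kdr 4.01-fold). Fabp4 rose 25.7-fold, the calcification inhibitor Mgp 11.2-fold, Muc5ac 31.2-fold [8.96-fold] and Grk1, the rhodopsin kinase, 32.6-fold [5.09-fold]. Of 21 corneal epithelial genes 3 fell (median -0.64; Dsg1a 3.08-fold, Wnt7a 2.60-fold with log2 ratios of -1.05 to 0.21 for its other probe sets, Trp63 2.36-fold). In all 1603 genes were higher and 402 lower of 12982 compared, the largest count of the 4 array pairs. Of the genes compared in both, 1007 were higher both here and with infection without DT, against 147 if the comparisons were independent. Both use the mock array without DT as denominator, and unchanged arrays simulated with the spread between probe sets shared 5.61 such genes on average. The simulated arrays held no variation between pools, so they cannot tell how many genes a differing mock pool alone would give.

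Muscle genes had some of the largest differences between the infection responses with and without DT. Square brackets give the difference with the floor at the 10th percentile where an array had no present call or the value changed with that floor. Differences that use an array without a present call have no rank. Myl1 had a difference of -7.78 on the log2 scale, Fabp4 -6.71, Smpx, a small muscle protein, -8.48 [-4.91], Myh4 -7.10 [-5.58] and Tnnc2, fast troponin C, -6.80 [-6.80]. Of 20 macrophage markers 14 had a response at least 2-fold smaller with DT (median difference -1.71) and of 23 chemokines 12 had (median -1.07). The same held for 3 of 8 MHC class II genes (median -0.70) and 5 of 13 NK markers (median -1, with 898 of 10000 random lists lower, and -0.31 with the floor at the 10th percentile). Interferon gamma induced genes had a median difference of 0.03, and type I interferon stimulated genes 0.54, with 7 of 30 at least 2-fold larger and 2 smaller with DT. Proliferation genes had a larger response with DT in 10 of 21 cases (median 0.98). Ska1 had a difference of 3.35 [2.07] and the centromere gene Oip5 2.44 [0.98]. Other large positive differences included those of Pabpc4l (2.55 [-0.12]), Fbxw22 (2.45 [2.45]), Neu3 (2.09 [1.08]) and Hace1 (2.02). Stromal genes had a smaller response with DT in 15 of 20 cases (median -1.52). In all, 404 genes had a larger and 1752 a smaller response with DT of 13524 compared. Without genes 2-fold apart between the mock arrays, 145 and 357 were left. Several of these list differences change with the choice of mock array. With the mock arrays exchanged, the arrays of each ratio also differ in DT. For a gene, the gap between arms is then the sum of its DT ratios in infected and mock corneas. In the main comparison it is the DT ratio in infected minus that in mock corneas. The exchange is thus no independent check of the order of the arms. MHC class II genes, whose DT medians were negative in both pairs, kept that order, as did NK markers. The exchanged medians were 1.36 without and -0.65 with DT for MHC class II genes, and 0.40 and -0.15 for NK markers. In the same order, the medians were 0.84 and 0.78 for macrophage markers, 1.28 and 1.39 for chemokines, 2.14 and 0.65 for type I interferon stimulated genes, 0.85 and -0.40 for proliferation genes and 0.52 and 0.66 for stromal genes, and among these 5 lists the order of the arms turned for all but the macrophage markers. Interferon gamma induced genes had infection medians of 1.36 without and 1.26 with DT, and of 2.00 and 0.60 with the mock arrays exchanged. Their small difference thus also changes with the exchange, which brings in the DT ratio of the mock corneas.

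The authors' deposited table flags 262 probe sets as 1 and 297 as 2. All of them were among 577 probe sets that met 3 criteria recomputed from the deposited values: an increase call for infection without DT, a decrease call for DT in infected corneas, and a rise in signal with infection that was smaller with DT, by the share named in the file header. Those flagged 1 had no change call for DT in mock corneas, and those flagged 2 had such a call, 281 an increase and 16 a decrease. Flag 1 in the authors' deposited table marks Gzma, Gzmb, Klrd1, H2-Aa, H2-Ab1, Cxcl9 and Ccl5, and flag 2 marks Cd74, H2-Eb1 and Cxcl10 together with 12 of the 20 stromal and 8 of the 12 muscle genes of the lists.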

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

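The tests of explanations below were chosen after the results were seen. In them the spread of a list median is a standard error from the variation between list members. For a difference of medians it combines both. List members are genes of the same pools and not replicates, so this spread holds no variation between pools. The named genes and lists given here moved at least 2-fold in opposite directions, either with infection in the arms with and without DT or with DT in mock and infected corneas, each arm being 1 pair of arrays, and none of these differences was tested. The value is the infection log2 ratio with DT minus that without DT, which for a gene is also the DT ratio in infected minus that in mock corneas. Square brackets give it with the floor at the 10th percentile of present signals, where an array had no present call or the value changed with that floor, and values that use an array without a present call have no rank.

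Most of these were muscle genes: Smpx -8.48 [-4.91], Myl1 -7.78, Myh4 -7.10 [-5.58], Tnnc2 -6.80 [-6.80], Tnnt3 -6.56 [-5.74], Mb -6.03, Myh3 -5.99 [-3.92], Atp2a1 -5.15, Ckm -5.11, Acta1 -5.10, Myh1 -4.88 and Pvalb -4.21. The muscle list median differed by -4.88 [-4.12] between the infection comparisons and by -4.61 [-4.49] between the DT comparisons. Adipocyte genes did the same, Adipoq by -8.18 [-4.77] and Fabp4 by -6.71, as did the matrix genes Epyc by -4.86 [-3.30] and Aspn by -4.60 [-3.98]. Mmp3 (-4.12) and Ms4a6d (-3.18 [-2.84]) rose with DT in mock corneas and fell with DT in infected corneas. The mast cell and eosinophil list median differed by -2.58 [-1.39] between the DT comparisons. Ska1 (3.35 [2.07]) and Fbxw22 (2.45 [2.45]) fell with infection without DT and rose with DT.

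Muscle and stromal genes were low on the mock array without DT relative to the other 3. Infection as the whole cause is argued against by the muscle median of -1.48 for infection with DT, and DT as the whole cause by that of -1.44 for DT in infected corneas. More adjoining tissue in the other pools may account for it but stays open: between the mock corneas the vessel median was 1.23, while the conjunctiva median was 0.269 with a spread of 0.6. A joint effect of toxin and virus on these genes was not tested. The ratios that use this mock array carry the difference whatever its origin.

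With DT, 4 of 8 MHC class II genes were 2-fold lower in infected and 2 of 8 in mock corneas. In mock corneas the MHC class II median minus the stromal median was -1.57, which argues against less adjoining tissue as the cause there, because stromal genes were higher with DT. In infected corneas the same difference was -0.43 with a spread of 0.46, and the muscle (-1.44, spread 0.35) and MHC class II (-1.09, spread 0.45) medians lay within their spread, while vessel and corneal epithelial medians were both -0.02, so tissue makeup and loss of cells cannot be told apart for that pair. A loss of CD11c-positive cells after DT could give the MHC class II median of -0.63 in mock corneas, but the dendritic and Langerhans cell median there was 0.86, with many members near the detection floor, so this cannot be told either. The corneal epithelial and interferon gamma induced medians in mock corneas were both -0.64. Other differences between these pools were therefore not excluded as the origin of the lower MHC class II median.

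Of 20 macrophage markers 5 fell with DT in infected corneas. Their median of 0.69 in mock corneas does not decide on a loss of macrophages after DT in both pairs. Stromal genes were also higher with DT there (median 0.93), so the pools differed in makeup. The tissue makeup of the pools may account for the pattern. In infected corneas the macrophage median was -0.80 (spread 0.16) and the stromal median -0.66 (spread 0.13). In mock corneas, where both were higher with DT, the macrophage median differed from the stromal median by -0.24, within their spread of 0.33. Vessel genes, though, had a median of -0.02 in infected corneas. An effect of DT on the recruitment of macrophages to infected corneas stays open and was not tested.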

How the results depend on the processing

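The mock array as denominator and the treatment of dim signals moved most counts by over 1.5 times. Causes were not tested beyond what each alternative does by construction. Counts are given as higher/lower for infection without DT (main 1439/339), infection with DT (214/157), DT in infected corneas (35/247), DT in mock corneas (1603/402) and the difference of responses (404/1752), in this order. A pseudocount of 50, which shrinks the ratios of dim genes, gave 472/137, 80/26, 0/59, 627/113 and 82/630. No filter, which adds genes without a present call, gave 2454/1037, 808/902, 749/919, 2695/952 and 1255/3067. A 3-fold threshold gave 528/59, 81/51, 4/81, 630/42 and 66/748. The floor at the 10th percentile left 102 lower for infection with DT and 13 higher for DT in infected corneas, and the 25th percentile filter left 93 and 11. The other counts under these floors and filters, and all counts under quantile normalization, centring and the mean of all probe sets, stayed within 1.5 times.

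These 3 alternatives were chosen after seeing the data. With the other mock array as denominator, infection without DT gave 425/112 and infection with DT 1380/392. Changes beyond both mock arrays numbered 265/24 and 100/29. Without genes 2-fold apart between the mock arrays, DT in infected corneas gave 23/128 and the difference 145/357.

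With the other mock array, the type I interferon stimulated median was 2.14 without DT and 0.65 with DT (main 1.13 and 1.56). The muscle median without DT was 0.0781. It was 1.52 with the pseudocount, 2.93 with the floor and 2.997 with the mean of probe sets (main 3.41), and in mock corneas 1.68 with the pseudocount (main 3.17). For DT in infected corneas the NK median (main -1.29) was -0.20 with the pseudocount, -0.0128 with the floor, -0.75 with the mean of probe sets and -0.75 over all measured members, and the MHC class II median (main -1.09) was -1.57 with the mean of probe sets.

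With the other mock array 20 list medians changed sign, and the exchanged medians were not ranked. For 9 of them the median against the own mock array lay within the range of most random lists, such as MHC class II with DT (0.10, then -0.65). The other 11, whose own-mock medians lay in the outer 2.5% of random lists at either end, became, without DT, the mast cell (-0.17), vessel (-0.14) and proliferation (0.85) medians, and with DT those of interferons and their receptors (-0.21), mast cells (0.25), pathogen sensing (-0.0442), stroma (0.66), muscle (1.30), vessels (0.99), proliferation (-0.40) and p53 targets (-0.0364). Over all measured members the interferon and receptor median with DT was -0.11. Of 168 list medians, 167 under quantile normalization and 168 under centring moved by less than the spread between probe sets. Of 138 named gene values, none that passed the 2-fold count reversed under these scalings or the floor, and Itgax and Ncr1 in mock corneas, below 2-fold, changed sign with the floor, to 0.18 and 0.24. With the pseudocount 124 moved by more than that spread. Centring shifted the median of all genes by -0.125 for infection without DT, -0.114 for DT in mock corneas and 0.11 for the difference. The planned use of the second deposited table was not run, since its signals were the same. Signals near the 10th percentile of present signals, where most NK and dendritic cell markers lie, limit what these arrays show.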

Other observations

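Mast cell and adipocyte transcripts differed between the pools. Mcpt4, a connective tissue mast cell chymase, had signals of 1.2, 27.7, 36.5 and 11.1 on the mock and infected arrays without DT and the mock and infected arrays with DT, with a present call on the infected array without DT alone. Tpsab1, a tryptase, had 10.2 without a present call, 49.6, 46.3 and 21.8, and Fabp4, an adipocyte fatty acid carrier, 21.1, 289.3, 543.2 and 71.1. Grk1 rose in mock corneas with DT along with the rod gene Pde6b, which was 2.24-fold higher there, and the lens filament genes Bfsp1 and Bfsp2 were 2.32-fold and 2.28-fold lower.

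Leukocyte adhesion genes rose with infection without DT in 6 of 10 cases and fell in 1. The integrin Itgal rose 10.2-fold [2.92-fold], its partner Itgb2 7.03-fold and Vcam1, the endothelial ligand of another integrin, 4.25-fold. With DT 1 of 9 rose, the addressin Madcam1 (2.19-fold). Complement genes rose in 8 of 13 cases without DT, including C1qb (5.06-fold) and C1qc (4.14-fold), fell in 1, Cd55 (2.09-fold), and rose in 1 of 13 with DT, Cfb (2.52-fold). Against the mock array of the other arm, 7 of 13 complement genes rose without DT (median 1.01) and 5 of 13 with DT (0.91), and 6 of 10 and 3 of 8 adhesion genes. Of 11 MHC class I genes 2 rose in either pair: Nlrc5, the class I transactivator, rose 5.66-fold without and 3.91-fold with DT, and the peptide transporter Tap1 2.39-fold and 2.08-fold. With the mock arrays exchanged, 6 of 11 class I genes rose without DT and 1 of 11 with DT. Immediate early genes rose in 4 of 14 cases without DT and 2 of 14 with DT, where Egr1 rose 2.19-fold and 2.59-fold. With the mock arrays exchanged, 0 of 14 and 4 of 13 rose.

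Some spike-in transcripts stood apart on the mock array with DT. The ratio of 5' to 3' signal of the Dap spike was 0.312 there and 0.521, 0.545 and 0.542 on the mock and infected arrays without DT and the infected array with DT, and that of the Thr spike was 0.234 against 0.411, 0.578 and 0.473. The Phe spike had 0.847 against 1.13, 1.04 and 1.19, while the Lys spike, with 0.405 against 0.444, 0.384 and 0.378, lay within the range of the other arrays. Other probe sets of these spikes gave the reverse for Phe and Lys, and again the lowest ratio there for Dap and Thr. Their 5' and 3' Phe signals were 91.5 and 86.9 there, against 153.2 and 181.8, 128.5 and 130.7, and 108.0 and 89.3, a ratio within the range. For Lys they were 91.6 and 84.2 there, against 146.7 and 101.1, 114.7 and 86.1, and 104.2 and 67.1, the lowest ratio. The Actb ratio was 0.788 there against 0.863, 0.838 and 0.834. For Gapdh the ratio was 1.23 on both arrays with DT and 1.36 and 1.30 on those without. The type I interferon stimulated and proliferation genes that were lower on this array were not tested against this difference.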
